A study of Drosophila melanogaster with 24 samples.

How the data were processed

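The series profiled RNA of manually dissected brains of adult female Drosophila melanogaster kept in a light-dark cycle, with zeitgeber time (ZT) counted from lights on. Wild-type Canton S flies were compared with per0 flies, which carry a nonsense allele of the clock gene period. There were 16 libraries made with an amplification kit that does not select polyadenylated RNA (non-polyA), 2 per genotype at each of ZT0, ZT6, ZT12 and ZT18. A further 8 libraries made with a kit primed on polyadenylated RNA (polyA) covered ZT0 and ZT12, again with 2 per genotype and time. Reads were 100 nt long in the non-polyA and 75 nt in the polyA libraries. The labels call the mutant of the polyA libraries yw, per0, so that genotype and background markers differ together there. Flies were 3 to 5 days old, and 10 to 12 brains were taken per time point. The labels give 2 days of brain collection but tie no library to a day or to animals of its own, so that p-values measure only the spread between these samples. Differences between replicates correlated across genes between groups at r of -0.57 to 0.65 in non-polyA (13 of 28 pairs of groups above 0.1) and -0.07 to 0.06 in polyA, and a replicate block is among the alternatives. Call counts with and without that block had been seen before these correlations, with the rule for choosing between them already fixed.

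The authors deposited 1 table of RPKM values (reads per kilobase of feature and 1e6 reads) with 43331 transcript, 252461 exon and 209130 intron records, made with the aligner RUM. They also deposited 1 junction track per library with read counts across each splice junction. The RUM version, the genome build, and whether reads mapping to several places were counted are not given in the sources used here. Value times feature length fell on whole multiples of 1 step per library for 100% of the values checked (a value of at least 0.2, at most 50 reads, tolerance 0.1 read), from which whole reads per feature and the depth were worked out. Depth came to 22.3 to 32.6 M reads in the non-polyA and 16.4 to 20.2 M in the polyA libraries. Junction tracks held 1470707 to 2961994 reads in the non-polyA and 438359 to 983415 in the polyA libraries. As a check that tracks and columns belong together, junction reads per gene were correlated with the columns. In a first version 19 of 24 tracks were best matched by their own column. A second version, written after that outcome, compared within a protocol, scaled by depth and used genes with a mean of at least 100 junction reads, and there 24 of 24 matched their own column.

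For each of 16975 gene symbols the transcript record with the highest mean over the libraries of a comparison was used, which can differ between the protocols. Of these, 14483 symbols (85.3%) were found in the table that pairs gene names with identifiers. Genes with a mean of at least 1 RPKM over the libraries of a comparison were tested on log2(RPKM + 0.5) with limma 3.58.1 (R 4.3.3), with 1 mean per genotype and time, a mean-variance trend and no robust option. The wording fixed for the test left the trend open to 2 readings, and the other reading, without the trend, is among the alternatives. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Genotype was tested as per0 minus wild type averaged over times. The 24-h component was a joint F test of ZT0 minus ZT12 and ZT6 minus ZT18, whose combined size is given as peak minus trough on the log2 scale. The polyA libraries gave ZT12 minus ZT0 in each genotype. The difference between genotypes was tested for both kinds of time effect. The protocols were compared in wild type at ZT0 and ZT12.

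Gene lists were tested with camera at a preset correlation of 0.01, over 29 lists with at least 3 tested genes, and again with an estimated correlation. Exon usage was tested with diffSplice of limma on non-overlapping exons with a mean of at least 1 RPKM. Junctions with at least 10 reads in at least 2 libraries that share a donor or acceptor were tested with diffSpliceDGE of edgeR 4.0.16. The junction tracks carry the same strand sign throughout, so no strand was used. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

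The comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. By that rule the 8 core clock genes were named in every comparison. For genotype these were joined by the 10 largest changes in each direction among called genes whose per0 and wild-type libraries did not overlap. For time these were joined by up to 20 called genes with the smallest p, or the 10 with the smallest p where fewer than 5 passed. From each list described, 2 to 4 members with the smallest p were taken, from the protocol comparison the 10 largest changes in each direction, and from the splicing tests the 5 genes with the smallest p and those called in both protocols. Examples in the text are a selection from these. After the data were opened, 1 gene each was taken out of 2 lists, where they had been entered by mistake, before their values were viewed. The symbol of white was rewritten to that of the table when its values had been seen.

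The tests were also run on simulated data, after first fits of the gene tests to the deposited values had been seen, for single genes with 200 changed genes at 2-, 4- and 16-fold. Of genes changed 4-fold, 100% were called for genotype in both protocols, 22.4% for the wild-type 24-h component, 40.3% for that of per0 and 4.48% for its genotype difference. For ZT12 minus ZT0 in polyA, 97.0% were called in each genotype and 73.1% for the difference. False calls made up 2.44 to 10.8% of the calls of limma, 8.51 and 4.27% of the junction calls of the non-polyA and polyA libraries, and 11.3 and 22.4% of their exon usage calls. The list test, simulated after its results had been seen, recovered 81.7 to 100% of lists changed 1.5-fold and 100% of those changed 2-fold, with 4.76 to 16.7% of calls false. With an estimated correlation it recovered 55.0 to 100% and 93.3 to 100%, with 0 to 10.6% false. Genes were drawn independently there, so correlation between the genes of a list was not simulated, and the list test for time in per0 was not simulated.

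Alternatives were pseudocounts of 0.1 and 2, no filter or a mean of at least 5, quantile and median-ratio scaling, the median over a gene's records, limma without the trend or with sample weights, edgeR on the recovered reads, an adjusted p under 0.1, a replicate block, an additive model, any difference between the 4 times, and leaving out each library in turn. Chosen after seeing the data were leaving out 1 library of each of the 2 groups with the lowest correlation between replicates, the settings tried for the overlap of the protocols, the list test for time in per0, and the list test without each library in turn. Counting reads that map to several places could not be tried, since the table does not give them apart. Libraries were left out for single genes, counts, splicing and the planned list tests.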

Results

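RNA abundance was measured in brains of wild-type and per0 flies around the light-dark cycle. The 16 non-polyA libraries form 8 groups of 2 (both genotypes at ZT0, ZT6, ZT12 and ZT18), and the 8 polyA libraries form 4 groups of 2 (both genotypes at ZT0 and ZT12). Depth was 22.3 to 32.6 M reads per non-polyA library and 16.4 to 20.2 M per polyA library. Replicates correlated across genes at r = 0.928 (per0 ZT0, non-polyA) to 0.989 (wild-type ZT0, polyA) on the log2 scale, where genes are not independent replicates. The lowest values were those of per0 ZT0 and of wild-type ZT6 (0.933), both non-polyA. Groups are given as mean ± SD.

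The first question was which brain transcripts follow a 24-h cycle in wild type. In the non-polyA libraries tim, whose protein partners PER in the negative arm of the clock, rose from 11.1 ± 1.87 RPKM at ZT0 to 124 ± 34.7 at ZT12 and 129 ± 27.5 at ZT18 (n = 2 at each time). vri, a repressor of Clk, rose from 2.72 ± 0.335 at ZT0 to 39.9 ± 0.333 at ZT12 (n = 2 each). Clk, the transcriptional activator of the loop, moved the other way, from 12.7 ± 1.56 at ZT0 to 1.2 ± 0.11 at ZT12 (n = 2 each). per stood at 0.417 ± 0.0460 at ZT0 and 3.53 ± 1.06 at ZT12 (n = 2 each). Outside the loop, Dro, which encodes the antimicrobial peptide drosocin, was at 7.19 ± 0.362 at ZT6 and 0.130 ± 0.0607 at ZT18 (n = 2 each).

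Of 9323 genes, 12 passed the limma test of the 24-h component in wild type: tim, Dro, vri, Clk, CG17386, CG11407, a record at 3L 7763493 to 7764700, CG31300, Ugt35b, CG9377, per and CG10513. Peak minus trough on the log2 scale was 4.56 for tim (SE of each contrast 0.35, adjusted p = 0.000248), 3.65 for vri (SE 0.32, adjusted p = 0.000346), 3.1 for Clk (SE 0.27, adjusted p = 0.000346) and 2.21 for per (SE 0.31, adjusted p = 0.0304). cry, cwo, cyc and Pdp1 did not pass, with peak minus trough of 2.11, 0.84, 0.30 and 0.29. The call of per was lost in 9 of 16 runs without 1 library, with adjusted p up to 0.333 (without wild-type ZT12 replicate 2), and with a pseudocount of 2, no filter or a replicate block. Those of CG10513, CG9377, Ugt35b, the 3L record and CG31300 were lost in 9, 6, 3, 3 and 1 of 16, and those of tim, vri, Clk, CG17386 and CG11407 in none. That of Dro was kept in 14 runs and not tested without either wild-type ZT6 replicate, where its mean fell under 1 RPKM. That of CG9377 also ended in edgeR (adjusted p = 0.117), with a pseudocount of 0.1 (0.272) or no filter (0.0629), and that of CG10513 with no filter (0.0769) or a replicate block (0.0576). The adjusted p of cry was 0.439. The count was 7 without wild-type ZT18 replicate 1 or ZT0 replicate 2, 20 without ZT6 replicate 2, 22 without ZT18 replicate 2, and 7 without per0 ZT0 replicate 2 and wild-type ZT6 replicate 1 together, an alternative chosen after seeing the data that ended the calls of per, CG10513, CG9377, CG31300 and Ugt35b (adjusted p of 0.0595 to 0.0632) and left Dro untested. Since simulated 4-fold cycles were called in 22.4% of cases, 12 is not an estimate of how many genes cycle.

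**Figure D1:**
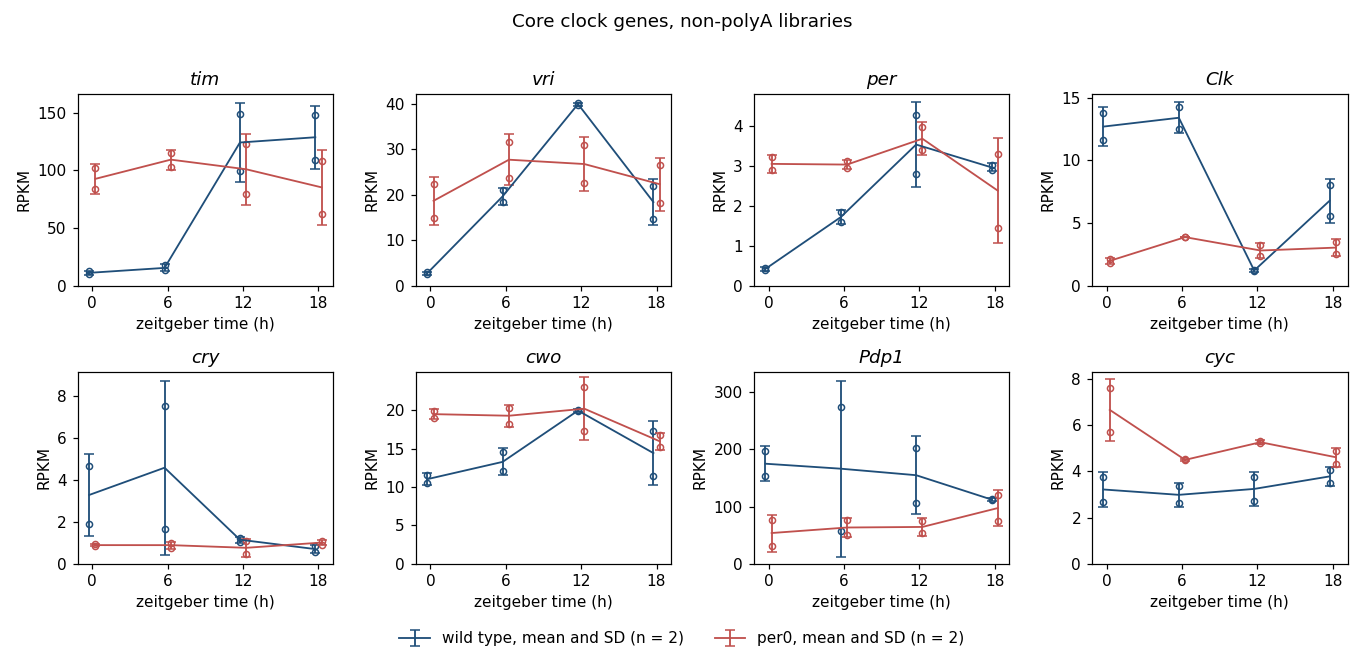
RPKM of the 8 core clock genes (vertical axes, linear from 0) against zeitgeber time in hours in the non-polyA libraries; circles are single libraries, lines join means and bars are SD (n = 2). tim, vri and per have their lowest wild-type mean at ZT0 (11.1, 2.72 and 0.417 RPKM), while the per0 means of tim stay between 85.3 and 109 RPKM.

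Several lists moved with time as groups in the wild-type non-polyA libraries, although single members mostly missed the threshold. Between ZT6 and ZT18, 59 annotated non-coding CR genes were higher at ZT6 by a median of 0.98, 163 small nucleolar RNAs by 0.58, 9 snoRNA host genes by 0.87 and 52 transfer RNAs by 0.41 on the log2 scale. The host gene Uhg1 was at 36.4 ± 6.84 RPKM at ZT6 and 10.5 ± 0.364 at ZT18 (n = 2 each), with adjusted p = 0.367. Not 1 member of these 4 lists passed over all genes, while 4 small nucleolar RNAs, 4 host genes and 1 transfer RNA passed when adjusted over the list alone. These were the 4 of 41 list calls that held with an estimated correlation (adjusted p = 0.0278 for each). Without wild-type ZT6 replicate 1, ZT6 replicate 2 or ZT18 replicate 1 none of the 4 held that way (adjusted p of 0.101 to 0.149), nor did the host genes without ZT18 replicate 2 (0.0608). At the preset correlation all 4 held without any 1 library, with a median of 0.48 for CR genes without ZT6 replicate 1 and of 0.19 for transfer RNAs without ZT18 replicate 1. Immune genes were higher at ZT6 by a median of 1.07 (1 of 21 called, Dro, and 6 higher and 1 lower adjusted over the list alone), with adjusted p = 1.55e-10 and, with an estimated correlation, adjusted p = 0.215. This rested on ZT6 replicate 1, without which the median was -0.38 (adjusted p = 0.602), and was 0.45 without ZT18 replicate 2 and 1.69 without ZT18 replicate 1. Mitochondrial genome genes were higher by 1.56 (0 of 19 called, 3 adjusted over the list alone; adjusted p = 1.15e-13, and 0.215 with an estimated correlation), by 0.74 without ZT6 replicate 2 and by 2.50 without ZT6 replicate 1. All mitochondrial reads together were 2.43 and 5.63% of the depth at ZT6 and 2.44 and 2.02% at ZT18. Between ZT0 and ZT12 the 8 core clock genes had a median of -0.42 (1 higher at ZT0, 3 lower; 1 and 4 adjusted over the list alone; adjusted p = 0.000163, and 0.291 with an estimated correlation). The summed reads of CR40 and CR41 loci on the unplaced and X heterochromatin sequences came to 138 and 65.4% of the depth in wild-type ZT6 replicates 1 and 2 and to 47.0 and 37.0% at ZT18, where reads counted at more than 1 record let the sum pass the depth. This share was thus higher at ZT6, as were the CR genes, small nucleolar RNAs, host genes and transfer RNAs. Whether the list calls follow from it was not tested.

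Markers of cell types and other lists were called in the same contrasts, with 0 members passing over all genes. Their 2 adjusted p are at the preset and at the estimated correlation, and none passed with the latter. At ZT6 13 muscle markers were higher than at ZT18 by a median of 0.19 (adjusted p = 9.48e-06 and 0.215), 7 long non-coding RNAs by 0.27 (0.00455 and 0.215) and 33 microRNA precursors by 0.16 (0.00455 and 0.0754). Lower were 24 ion channel and sleep genes, at -0.39 (0.00319 and 0.565). For ZT0 minus ZT12, 18 neuron and synapse genes had a median of -0.35 (adjusted p = 0.000162 and 0.483), muscle markers -0.49 (0.00564 and 0.6), ion channel and sleep genes -0.17 (0.00737 and 0.6) and 29 photoreceptor genes -0.21 (0.00951 and 0.716). Higher at ZT0 were 59 CR genes at 0.68 (3.96e-11 and 0.291), 52 histone genes at 0.68 (1.63e-11 and 0.483), 19 mitochondrial genes at 1.45 (1.63e-11 and 0.439) and 9 snoRNA host genes at 0.54 (6.5e-05 and 0.291). So were 77 ribosomal protein genes at 0.35 (0.000247 and 0.716), 30 neuropeptide genes at 0.40 (0.000911 and 0.6) and 52 transfer RNAs at 0.23 (0.0292 and 0.483).

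Without wild-type ZT0 replicate 2 the ZT0 minus ZT12 calls of ribosomal protein (median 0.10, adjusted p = 0.388), neuron and synapse (-0.09, 0.213), ion channel and sleep (-0.14, 0.213), neuropeptide (0.24, 0.198) and photoreceptor genes (-0.11, 0.213) and transfer RNAs (0.27, 0.11) were lost. Without ZT12 replicate 1 those of ribosomal protein (-0.12, 0.708), neuron and synapse (-0.34, 0.084), ion channel and sleep genes (-0.20, 0.157) and muscle markers (-0.78, 0.084) were. The call of muscle markers was lost without ZT0 replicate 1 too (-0.26, 0.163), and that of transfer RNAs without ZT12 replicate 2 (-0.05, 0.283). Medians also moved without ZT0 replicate 1, to 2.58 for mitochondrial, 0.83 for host, 0.60 for ribosomal protein and 0.65 for neuropeptide genes. There they also came to -0.61 for neuron and synapse, -0.28 for ion channel and sleep and -0.35 for photoreceptor genes and 0.37 for transfer RNAs. Mitochondrial genes were at 0.83 without ZT0 replicate 2. Without ZT12 replicate 1 the medians were 0.30 for histone genes, 0.20 for neuropeptide genes, -0.35 for photoreceptor genes and 0.47 for transfer RNAs. Without ZT12 replicate 2 they were 1.08 for histone, 0.80 for ribosomal protein and -0.05 for photoreceptor genes. Between ZT6 and ZT18 the calls of ion channel and sleep genes (-0.22, 0.133), microRNA precursors (-0.08, 0.26) and long non-coding RNAs (0.34, 0.336) were lost without ZT6 replicate 1. That of ion channel and sleep genes was lost without ZT18 replicate 2 too (-0.22, 0.472). Without ZT18 replicate 1 those of microRNA precursors (0.02, 0.166) and long non-coding RNAs (-0.12, 0.373) were lost. The latter was also lost without ZT6 replicate 2, ZT0 replicate 1 or ZT0 replicate 2 (0.23, 0.23 and 0.07, with adjusted p up to 0.237). Muscle markers kept theirs, at 0.11 without ZT18 replicate 1, 0.44 without ZT18 replicate 2 and 0.82 without ZT6 replicate 1. MicroRNA precursors were at 0.26 without ZT18 replicate 2 and 0.37 without ZT6 replicate 2.

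The next question was whether these cycles depend on per. In per0 non-polyA brains tim means lay between 85.3 ± 32.8 and 109 ± 8.68 RPKM, and Clk means between 1.97 ± 0.264 and 3.86 ± 0.00686 (n = 2 at each time), so that tim sat near the wild-type maximum and Clk nearer the wild-type minimum at every time. The 24-h component differed between genotypes for 5 of 9323 genes in limma: tim, with a difference of 4.77 (SE of each contrast 0.50, adjusted p = 0.0118), Clk (3.42, SE 0.38, adjusted p = 0.0125), CG17386 (4.67, SE 0.56, adjusted p = 0.0174), Dro (3.64, SE 0.46, adjusted p = 0.0248) and CG11407 (4.16, SE 0.57, adjusted p = 0.0440). vri missed the threshold with a difference of 3.14 (SE 0.45, adjusted p = 0.0539), as did per (2.14, SE 0.44, adjusted p = 0.656), cry, cwo, Pdp1 and cyc. vri passed with quantile or median-ratio scaling, a mean of at least 5 or edgeR, and per with quantile normalization or edgeR. The call of tim was lost without wild-type ZT12 replicate 2 or per0 ZT12 replicate 1 (adjusted p up to 0.0545). Those of Clk, CG17386 and CG11407 were lost in 7, 7 and 12 of 16 such runs and that of Dro in 11 of the 14 that tested it, and that of Dro ended in edgeR (adjusted p = 0.771), with a pseudocount of 0.1 (0.494) and with sample weights (0.115). That of CG11407 ended with no filter (0.0737), a pseudocount of 0.1 (0.0531) or a replicate block (0.0578). CG17386 kept a time effect in per0 polyA brains, where limma gave a log2 ZT12 minus ZT0 of -2.65 (SE 0.25, adjusted p = 0.00209), against -4.26 in wild type. In non-polyA it was 0.70 in per0 (SE 0.39) and -3.59 in wild type. A loss of its time effect in per0 thus rests on the non-polyA libraries alone.

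In per0 itself the 8 clock genes did not pass (adjusted p of 0.993 for tim) and 1 gene passed, CG7214, at 0.0752 ± 0.0586 RPKM at ZT6 and 6.06 ± 2.05 at ZT18 (n = 2 each, peak minus trough 3.48, SE 0.40, adjusted p = 0.0349). That call ended with a pseudocount of 2 (adjusted p = 0.0849), quantile (0.208) or median-ratio scaling (0.0946) and sample weights (0.215). Unadjusted p was under 0.05 for 269 of 9323 genes, a share below the 0.05 that no rhythm would give on average. In wild type CG7214 stood at 3.11 ± 1.77 at ZT6 and 12.3 ± 3.94 at ZT18 (n = 2 each). The per0 count was 171 without per0 ZT0 replicate 1, and 0 without either replicate of wild-type ZT0 or ZT18 or of per0 ZT6, ZT12 or ZT18, or without per0 ZT0 replicate 2. The genotype difference counted 66 genes without per0 ZT0 replicate 1, 13 without wild-type ZT18 replicate 2, and 3 without wild-type ZT6 or ZT18 replicate 1 or either per0 ZT6 replicate. It counted 2 without wild-type ZT0 replicate 1, and 1 without wild-type ZT12 replicate 1, wild-type ZT0 replicate 2, per0 ZT0 replicate 2 or per0 ZT12 replicate 2. It counted 0 without wild-type ZT12 replicate 2 or per0 ZT12 replicate 1, and 0 without per0 ZT0 replicate 2 and wild-type ZT6 replicate 1 together.

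The polyA libraries asked the same of dusk against dawn. In wild type tim rose from 14.6 ± 1.73 RPKM at ZT0 to 145 ± 12.3 at ZT12, vri from 1.83 ± 0.0438 to 68.1 ± 35.3 and per from 0.995 ± 0.114 to 7.11 ± 0.332, while Clk fell from 7.70 ± 0.640 to 1.14 ± 0.140 (n = 2 each). CG11407 fell from 137 ± 23.3 to 6.75 ± 0.688, and Ugt35b, a UDP-glycosyltransferase gene, from 220 ± 32.3 to 55.1 ± 6.80 (n = 2 each). gol, which encodes a ubiquitin ligase, rose from 40.1 ± 2.64 to 256 ± 95.5, and the nuclear receptor gene Hr38 from 2.26 ± 0.0451 to 8.16 ± 0.108 (n = 2 each). cwo passed narrowly (log2 1.23, SE 0.22, adjusted p = 0.0402), and Pdp1, cry and cyc did not pass (log2 0.85, -0.76 and -0.20).

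In all, limma called 77 of 10229 genes in wild type, 44 higher and 33 lower at ZT12. The log2 change was 3.27 for tim (SE 0.18, adjusted p = 4.9e-05), 4.78 for vri (SE 0.30, adjusted p = 0.000108) and -4.24 for CG11407 (SE 0.20, adjusted p = 2.92e-05), each in the same direction in every pair of ZT12 and ZT0 libraries. Of the 64 of these genes that were tested in the non-polyA libraries, 51 had the same sign of ZT12 minus ZT0 there. The count was 18 without wild-type ZT0 replicate 1, 17 without ZT0 replicate 2, 859 without ZT12 replicate 1 and 43 without ZT12 replicate 2. Lower calls were as many or more without ZT0 replicate 2 (7 higher, 10 lower), without ZT12 replicate 2 (20 and 23) and with quantile normalization (33 and 34), and edgeR gave 55 and 54. The call of Hr38 was lost without either wild-type ZT0 replicate (adjusted p up to 0.0775), that of Ugt35b without ZT0 replicate 1 (0.0568), and that of cwo in 7 of 8 such runs, as also with quantile or median-ratio scaling, no filter or no trend.

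By list, 5 of 26 immune genes were higher at ZT12 in wild type and 0 lower (12 adjusted over the list alone), with a median of 0.83 on the log2 scale. AttC, an attacin, rose from 5.99 ± 4.02 to 49.0 ± 7.33 RPKM, and Mtk, which encodes metchnikowin, from 11.6 ± 4.88 to 39.1 ± 4.20 (n = 2 each). In non-polyA, ZT12 minus ZT0 was -1.13 for Mtk (SE 0.73), -0.84 for DptB (SE 0.90) and 0.14 for IM4 (SE 0.51), called members tested there too, and the list, with a median of 0.22 for ZT0 minus ZT12, did not pass (adjusted p = 0.111). Of 8 clock genes 4 were higher and 1 lower (5 and 2 adjusted over the list alone). Of 20 heat shock genes 1 was higher, Hsp22 (3 adjusted over the list alone), and of 58 cytochrome P450 genes 2 were, Cyp12d1-p and Cyp12d1-d (9 adjusted over the list alone). Mitochondrial genome genes had a median of -1.45, with 1 of 22 lower (7 adjusted over the list alone), and of -2.39 without wild-type ZT12 replicate 1 and -0.78 without ZT12 replicate 2. All mitochondrial reads together were 3.84 and 3.77% of the depth at ZT0 and 3.44 and 6.38% at ZT12. Camera called immune genes (adjusted p = 6.55e-10), clock genes (0.00476), heat shock genes (4.44e-05), P450 genes (0.0012) and mitochondrial genes (4.71e-10). With an estimated correlation all 5 calls were lost, at adjusted p of 0.106, 0.373, 0.373, 0.686 and 0.373, and that of clock genes also without wild-type ZT12 replicate 1 (0.0768).

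Camera called 6 further lists in these libraries, each only at the preset correlation, whose adjusted p comes before that at the estimated one. Ribosomal protein genes were higher at ZT12 by a median of 0.31 (0 of 78 called, adjusted p = 0.0012 and 0.943) and oxidative stress genes by 0.33 (2 of 43 higher and 1 lower, 11 and 1 adjusted over the list alone; 0.00441 and 0.373). Neuron and synapse genes had a median of -0.27 (0 of 18 called, 0.00441 and 0.766), ion channel and sleep genes -0.16 (0 of 26, 0.00476 and 0.686), genes of clock kinases, phosphatases and turnover -0.24 (0 of 15, 0.0342 and 0.686) and microRNA precursors -0.08 (1 of 23 lower, 0.0253 and 0.373). Without wild-type ZT12 replicate 2 the calls of ribosomal protein (0.06, adjusted p = 0.751), neuron and synapse (-0.04, 0.626), ion channel and sleep (-0.03, 0.41) and clock kinase genes (0.06, 0.81) were lost. Oxidative stress genes were then at 0.21. Without ZT0 replicate 1 the clock kinase call (-0.15, 0.149) and without ZT0 replicate 2 the ion channel call (-0.09, 0.0842) were lost. That of microRNA precursors was lost in 6 of 8 runs (adjusted p up to 0.663, median -0.75 without wild-type ZT0 replicate 2). Without ZT12 replicate 1 the medians were 0.56 for ribosomal protein, -0.44 for neuron and synapse, -0.35 for ion channel and sleep and 0.49 for oxidative stress genes. Ion channel and sleep genes were at -0.25 without ZT0 replicate 1.

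In per0 polyA brains the 8 clock genes did not pass (log2 ZT12 minus ZT0 of -0.21 for tim, 0.35 for vri, 0.53 for per and -0.21 for Clk), while CG15784, Hsp22 and t, called in wild type as well, passed. CG15784 rose from 5.51 ± 1.48 RPKM at ZT0 to 513 ± 102 at ZT12, and ImpL3, the lactate dehydrogenase gene, from 4.67 ± 1.79 to 114 ± 42.9 (n = 2 each). Hsp22, a small heat shock protein gene, rose from 5.19 ± 0.318 to 71.1 ± 7.71, Arc1 from 19.8 ± 0.333 to 172 ± 56.8 and Arc2 from 1.48 ± 0.371 to 13.3 ± 0.914 (n = 2 each), the last 2 being homologs of the activity-regulated cytoskeleton gene. t, which encodes an enzyme that frees dopamine and histamine from their beta-alanyl conjugates, fell from 49.7 ± 0.815 to 16.8 ± 1.38 (n = 2 each), and in wild type from 71.6 ± 9.01 to 23.9 ± 5.09 (n = 2 each).

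Limma called 23 genes in per0, 15 higher and 8 lower at ZT12, of which 6 were also called in wild type in the same direction (CG15784, CG17386, Hsp22, MIP22634, Nplp3 and t) against 0.173 for independent lists. Both tests use the same estimate of spread for a gene, so these lists are not independent and 0.173 may be too low. Of the 15 called genes that were tested in the non-polyA libraries, 8 had the same sign of ZT12 minus ZT0 in per0 there. The count was 13 without either wild-type ZT0 replicate, 8 without per0 ZT0 replicate 1, 11 without per0 ZT12 replicate 1, 46 without per0 ZT0 replicate 2 and 12 without per0 ZT12 replicate 2. Higher calls were not the more numerous without per0 ZT0 replicate 2 (16 higher, 30 lower), in edgeR (16 and 17) or with a mean of at least 5 (10 and 11). The call of t in per0 was lost without per0 ZT0 replicate 1, ZT12 replicate 1 or ZT12 replicate 2 (adjusted p up to 0.179), that of CG17386 without per0 ZT0 replicate 1 (0.0517) and that of Nplp3 without per0 ZT0 replicate 1 or ZT12 replicate 1 (up to 0.163). In wild type that of t was lost without either ZT0 replicate (up to 0.0933) and that of MIP22634 without ZT0 replicate 1 (0.0734). A list test added after the data were seen gave heat shock genes a median of 0.37 (1 of 20 higher; adjusted p = 0.000548) and snoRNA host genes 0.60 (0 of 9 called, 4 adjusted over the list alone; adjusted p = 0.000286), both at 0.623 with an estimated correlation. It also called, with adjusted p at the preset and the estimated correlation, small nucleolar RNAs (0.39, 0.00266 and 0.623), microRNA precursors (0.62, 0.0415 and 0.623), CR genes (-0.20, 0.00039 and 0.754) and transmitter genes (-0.21, 0.0132 and 0.623). The last 2 were odorant-binding proteins (-0.16, 0.0415 and 0.754) and ion channel and sleep genes (-0.09, 0.0415 and 0.754), and the test was not repeated without single libraries.

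ZT12 minus ZT0 differed between genotypes for 28 genes, 16 more positive and 12 more negative in per0. CG15784 had a difference of 4.85 on the log2 scale (SE 0.32, adjusted p = 0.000655), tim -3.48 (SE 0.25, adjusted p = 0.000655), CG11407 3.67 (SE 0.28, adjusted p = 0.000851), vri -4.42 (SE 0.43, adjusted p = 0.00467) and ImpL3 3.92 (SE 0.42, adjusted p = 0.00593). Clk differed by 2.12 (SE 0.32, adjusted p = 0.0326), a call lost in 6 of 8 runs without 1 library and with a replicate block, no filter or the median over records. per did not pass at -1.82 (SE 0.32, adjusted p = 0.0643) but did in edgeR (adjusted p = 0.00614), and cwo, Pdp1, cry and cyc did not pass. The count was 10 without wild-type ZT0 replicate 1, 77 without wild-type ZT12 replicate 1, 11 without wild-type ZT0 replicate 2 or per0 ZT0 replicate 1, and 14 without either per0 ZT12 replicate. More negative calls were the more numerous with a mean of at least 5 (12 positive, 15 negative), in edgeR (16 and 21), at an adjusted p under 0.1 (21 and 22) and without per0 ZT0 replicate 2 (15 and 24).

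**Figure D2:**
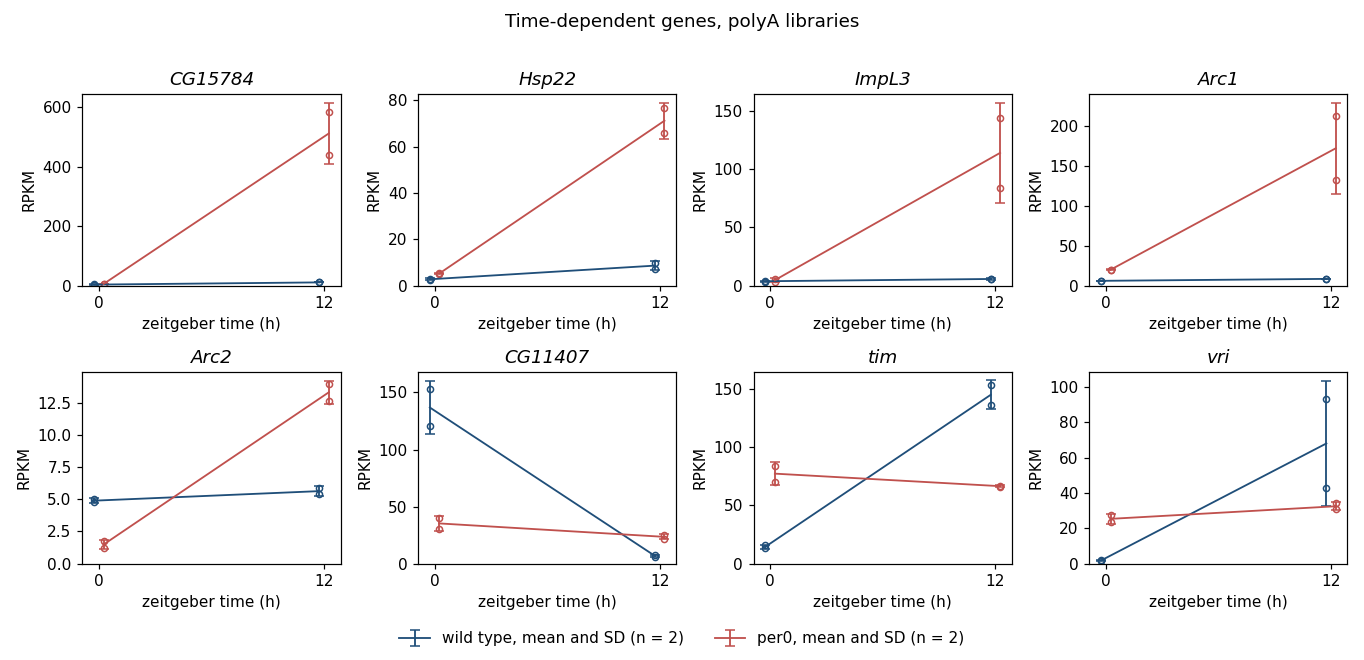
RPKM of 8 genes with a time effect (vertical axes, linear from 0) against zeitgeber time in hours in the polyA libraries; circles are single libraries, lines join means and bars are SD (n = 2). CG15784 reaches 513 RPKM at ZT12 in per0, and tim reaches 145 RPKM at ZT12 in wild type against 66.5 in per0.

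Averaged over time, per0 differed from wild type for many transcripts outside the clock. In the non-polyA libraries mthl8, a methuselah-like receptor gene, was at 9.09 ± 2.09 RPKM in per0 and had no reads in wild type (n = 8 each), at least 171-fold higher against a floor of 3 reads per library. Kmn1, a kinetochore gene, was at 1.03 ± 0.25 in per0 and 15.6 ± 2.35 in wild type, and CG11697 at 0.0275 ± 0.0644 and 4.81 ± 0.990 (n = 8 each). p24-2 was higher in per0, at 7.75 ± 3.49 against 0.484 ± 0.0935 (n = 8 each). Among clock genes Clk was lower in per0 (log2 -1.04, SE 0.14, adjusted p = 0.000217), and tim (1.22, SE 0.18, adjusted p = 0.000512), cyc (0.59, SE 0.13, adjusted p = 0.0111) and vri (0.68, SE 0.16, adjusted p = 0.0132) were higher.

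Limma called 1098 of 9323 genes, 597 higher and 501 lower in per0. Lower calls were the more numerous with median-ratio scaling (693 higher, 762 lower), in edgeR (743 and 789), without per0 ZT0 replicate 1 (678 and 739) and without per0 ZT18 replicate 1 (513 and 581), while 828 were higher and 429 lower without per0 ZT18 replicate 2. Many of the largest changes were in unnamed records, such as nc_20985 on chromosome 4 (1341569 to 1342169), at 0.0577 ± 0.108 RPKM in per0 and 98.4 ± 16 in wild type (n = 8 each). The calls of per (log2 0.59, SE 0.16, adjusted p = 0.0269) and Pdp1 (-1.07, SE 0.31, adjusted p = 0.0403) were lost in 11 and 12 of 16 runs without 1 library, at adjusted p up to 0.0736 and 0.106, that of per with a pseudocount of 2 (0.0518), and that of Pdp1 with no filter (0.0581) or the median over records (0.124). The additive model, in which a genotype difference in timing enters the spread, ended the calls of Clk (adjusted p = 0.0508), tim (0.0918), vri (0.186) and per (0.153). cry and cwo did not pass (log2 -0.75 and 0.37), while cry passed in edgeR (adjusted p = 0.0209) and both with quantile normalization (0.0386 and 0.0485), and cry with median-ratio scaling (0.0467). Since per0 is a nonsense allele, the level of per mRNA is no check of the genotype labels. The count was 729 without per0 ZT12 replicate 1.

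By list, immune genes were lower in per0 non-polyA brains, with 8 of 21 lower and 0 higher (11 lower adjusted over the list alone) and a median of -0.90 on the log2 scale (-0.52 without wild-type ZT6 replicate 1). The stress-induced humoral factor genes TotA and TotC were at 3.22 ± 1.96 RPKM in per0 against 55.5 ± 51.5 in wild type and at 0.514 ± 0.410 against 12.8 ± 8.92 (n = 8 each). Mitochondrial genome genes had a median of -1.14, with 5 of 19 lower (9 adjusted over the list alone), among them the large ribosomal RNA mt:lrRNA at 426 ± 142 against 977 ± 598 (n = 8 each). Transfer RNAs had a median of -0.28, with 2 of 52 higher and 4 lower (3 and 9 adjusted over the list alone). Camera called these 3 of 29 lists (adjusted p = 3.21e-05, 2.47e-06 and 0.0357), and with an estimated correlation adjusted p was 0.948 for each. The call of transfer RNAs was lost without wild-type ZT12 replicate 1 (adjusted p = 0.13), wild-type ZT6 replicate 1 (0.0716) or per0 ZT12 replicate 1 (0.0629).

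In the polyA libraries Eh, the eclosion hormone gene, was at 28.1 ± 3.94 RPKM in per0 and 1.31 ± 0.739 in wild type, and the cytochrome P450 gene Cyp6a17 at 37.1 ± 3.91 and 0.149 ± 0.102 (n = 4 each). The transcript record used for mbl, a regulator of splicing, was lower in per0, at 59.1 ± 31.5 against 818 ± 78.7, and CG11697 was again lower, at 0.0833 ± 0.0822 against 35.5 ± 3.11 (n = 4 each). Exons of mbl did not all fall: that at 2R 13250254 to 13252891 was at 5.54 ± 1.25 in per0 and 2.71 ± 0.938 in wild type (n = 4 each). Among clock genes vri (log2 1.26, SE 0.21, adjusted p = 0.0034), tim (0.63, SE 0.12, adjusted p = 0.00755) and cwo (0.66, SE 0.15, adjusted p = 0.0162) were higher, and Clk (-0.67, SE 0.16, adjusted p = 0.0168) and cry (-0.65, SE 0.15, adjusted p = 0.0171) lower. per passed narrowly (0.55, SE 0.16, adjusted p = 0.0368), and Pdp1 and cyc did not pass (0.42 and -0.03). The averages are over log2 values: on the linear scale vri was at 29.0 ± 4.60 in per0 and 35.0 ± 43.4 in wild type and tim at 71.9 ± 8.34 and 79.8 ± 75.6 (n = 4 each), since wild type was far higher at ZT12 alone.

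Limma called 2061 of 10229 genes, 935 higher and 1126 lower in per0. The count was 1051 without wild-type ZT0 replicate 1, 1099 without wild-type ZT0 replicate 2, 1370 without per0 ZT0 replicate 1 and 1148 without per0 ZT12 replicate 2, and 584 were higher and 846 lower without per0 ZT12 replicate 1. The call of tim was lost without wild-type ZT0 replicate 2 (adjusted p = 0.053), and those of per, Clk, cry and cwo in 7, 4, 4 and 3 of 8 runs. The additive model ended those of vri (adjusted p = 0.254), tim (0.465), cwo (0.0593), Clk (0.225) and per (0.258), and no filter (0.0651) or a pseudocount of 2 (0.0852) that of per. The eye colour gene white, which the label yw, per0 names, did not pass (log2 -0.60, SE 0.22, adjusted p = 0.0819).

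By list, photoreceptor transcripts were lower in per0 polyA brains, with 11 of 29 lower and 0 higher (16 lower adjusted over the list alone) and a median of -0.57. trpl, a phototransduction channel gene, was at 311 ± 50 RPKM against 668 ± 165, and ninaC, a photoreceptor myosin gene, at 204 ± 43.3 against 343 ± 50.7 (n = 4 each). The rhodopsin transcript ninaE took 2.27 to 3.11% of the reads in per0 and 3.94 to 5.22% in wild type. Of 20 heat shock genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone), among them Hsp70Aa at 26.4 ± 7.67 against 5.95 ± 2.49 (n = 4 each). Mitochondrial genome genes had a median of 0.95 with 7 of 22 higher (8 adjusted over the list alone), opposite in sign to the non-polyA libraries. The 7 were all mitochondrial tRNAs, mt:lrRNA had log2 -0.15, and all mitochondrial reads together were 3.67 to 5.68% of the depth in per0 and 3.44 to 6.38% in wild type. Ribosomal protein genes had a median of -0.27 with 5 of 78 lower (1 adjusted over the list alone), and small nucleolar RNAs a median of 0.22 with 16 of 114 higher and 6 lower (16 and 5 adjusted over the list alone). Camera called these 5 lists (adjusted p = 0.000303, 0.000303, 0.00249, 0.00726 and 0.0465), and with an estimated correlation adjusted p was 0.918 for each. Without wild-type ZT12 replicate 2 the calls of mitochondrial genes (median 0.47, adjusted p = 0.0914), ribosomal protein genes (-0.16, 0.262) and small nucleolar RNAs (0.24, 0.0965) were lost. The second was lost without per0 ZT0 replicate 1 too (-0.15, 0.0653), where small nucleolar RNAs were at 0.35, and the third without per0 ZT0 replicate 2 (0.10, 0.192), while it was at 0.15 without per0 ZT12 replicate 1.

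**Figure D3:**
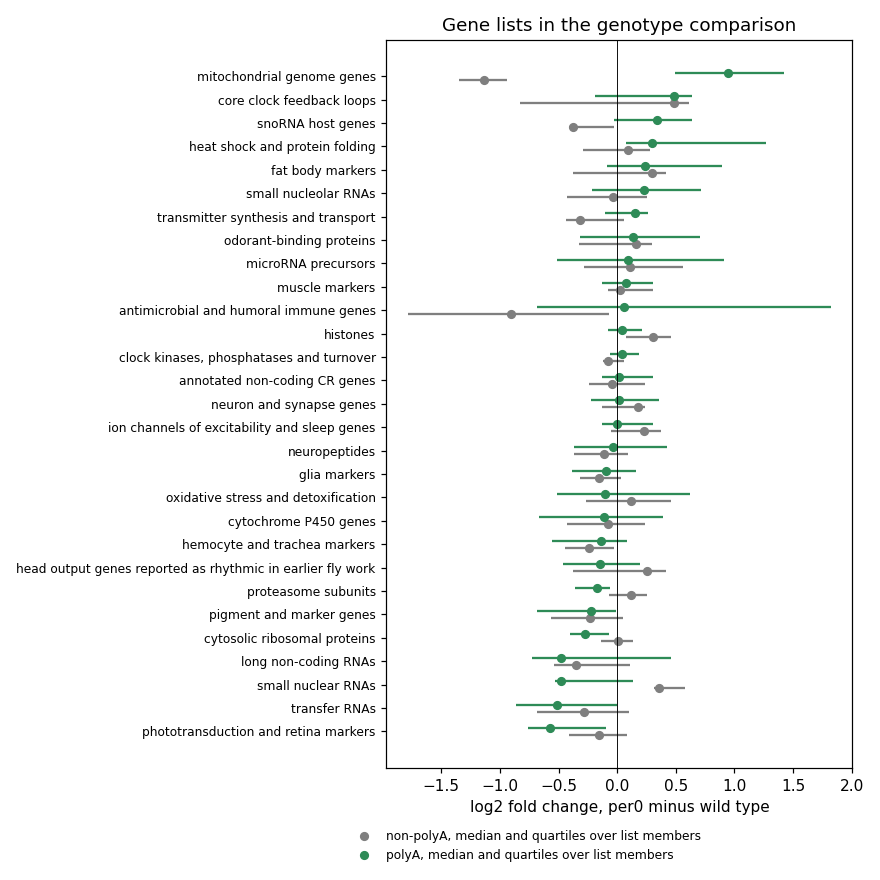
Median (point) and quartiles (line) over list members of the log2 fold change of per0 minus wild type (horizontal axis) for each gene list (vertical axis), in non-polyA and polyA libraries. Mitochondrial genome genes lie at -1.14 in non-polyA and 0.95 in polyA, and photoreceptor genes at -0.15 and -0.57.

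The protocols were separate libraries with their own wild-type controls, so that their genotype calls can be set side by side. The labels do not say whether both were made from the same brains, so an overlap is not shown to be one between separate animals. Of 8285 genes tested in both, 87 were called higher in per0 in both and 121 lower in both, against 39.9 and 48.5 for independent lists, and 70 were called in opposite directions against 88.5. CG11697 and Kmn1 were among those lower in both, Kmn1 at 13 ± 1.98 RPKM in per0 and 107 ± 18.6 in wild type in the polyA libraries (n = 4 each). Of 900 non-polyA calls among these genes, 59.0% had the same sign in polyA. Genes were matched by name, so the values of a gene in the 2 protocols can come from different transcript records. Across all 8285 genes, which are not independent replicates, the fold changes had Pearson r = 0.126, Spearman rho = 0.00252 and a covariance of 0.0364. ZT12 minus ZT0 in wild type gave 4 genes higher and 5 lower in both protocols, against 0.0164 and 0.0253, and 0 called in opposite directions.

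In wild type at ZT0 and ZT12 the polyA libraries were compared with the non-polyA ones. Ribosomal protein transcripts were far higher in polyA, with RpL18 at 405 ± 83.0 RPKM against 1.40 ± 0.456 and RpS6 at 874 ± 237 against 4.26 ± 1.10 (n = 4 each). The non-coding CR40640 was at 10.2 ± 1.75 in polyA and 142077 ± 57710 in non-polyA, and CR40639 at 14.3 ± 3.27 and 164812 ± 70748 (n = 4 each). cry (log2 4.23, SE 0.25, adjusted p = 3.85e-08) and cyc (2.41, SE 0.17, adjusted p = 1.86e-07) were higher in polyA, and Pdp1 (-1.05, SE 0.22, adjusted p = 0.000944) and cwo (-0.75, SE 0.17, adjusted p = 0.00163) lower. Limma called 9316 of 10594 genes, 7050 higher and 2266 lower in polyA, with a median of 1.36 on the log2 scale. Median-ratio scaling moved that by -1.43 and gave 4274 higher and 4533 lower, and quantile normalization gave 4864 and 3940. per, at 0.82 (SE 0.18), turned to -0.34 with median-ratio scaling and -0.14 with quantile normalization, so its direction rests on the scaling. Clk passed narrowly (-0.37, SE 0.16, adjusted p = 0.0446; lost in 6 of 8 runs without 1 library, with a mean of at least 5, no filter, a pseudocount of 0.1 or a replicate block), and tim and vri did not pass (0.32 and -0.02) except, as lower in polyA, with either scaling (tim at -1.22 and -0.57, vri at -1.42 and -0.95). Kit, read length (75 nt in polyA, 100 nt in non-polyA) and any difference in collection cannot be separated here.

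The exon records asked whether the genotypes use different exons of the same gene. In the non-polyA libraries an exon of Mical, which encodes an actin-oxidizing enzyme, at 3R 5863538 to 5863612 was at 49.7 ± 17.0 RPKM in per0 and 2.29 ± 0.980 in wild type (n = 8 each). An exon of Dscam, the neuronal recognition gene with arrays of alternative exons, at 2R 3248031 to 3248154 was at 5.77 ± 2.82 and 22.7 ± 8.77 (n = 8 each). In the polyA libraries an exon of unc-104, a kinesin of synaptic vesicle transport, at 2R 12649173 to 12649312 was at 226 ± 25.8 against 5.98 ± 1.73, and one of Tequila at 3L 9069419 to 9069895 at 42.0 ± 5.24 against 0.142 ± 0.0436 (n = 4 each). The same Tequila exon was at 6.20 ± 2.41 against 2.13 ± 0.754 in the non-polyA libraries (n = 8 each).

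The diffSplice test of limma called 963 of 7492 genes in non-polyA, with Dscam, CG17684, Mical, trol and Uhg5 first. It called 781 of 7713 in polyA, with unc-104, Tequila, Caki, l(1)G0196 and mbl first. Of 6527 genes tested in both, 198 were called in both against 95.4 for independent lists. This counts gene names, whichever exon changed and in whichever direction, and overlapping records with separate names count apart. Relative to the rest of its gene, the Tequila exon was higher in per0 in both protocols (log2 6.98 in polyA, 3.23 in non-polyA). An exon of Gpdh at 2L 5947488 to 5947629 went opposite ways (1.91 and -1.12). On simulated data 11.3 and 22.4% of the calls were false. The count was 1454 without per0 ZT0 replicate 1 in non-polyA. In polyA it was 384 without wild-type ZT0 replicate 1, 413 without wild-type ZT0 replicate 2, 471 without per0 ZT0 replicate 1, 1488 without per0 ZT0 replicate 2 and 412 without per0 ZT12 replicate 2.

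Splice junctions also differed in their share of reads between genotypes. In Ggamma30A, a G protein subunit gene, a junction at 2L 9256815 to 9256892 took 9.28 ± 4.98% of its cluster in per0 and 0.0453 ± 0.0281% in wild type (n = 8 each; 45842 and 362 reads). In shakB, a gap junction gene, a junction at X 20698268 to 20699956 took 0.10 ± 0.108% against 28.4 ± 8.79% (n = 8 each; 4 and 1706 reads). In CG12194 a junction at 2L 4840984 to 4841162 had all reads of its cluster in wild type and 0 in per0 in both protocols (66 reads in non-polyA, 72 in polyA). In Nrx-1, the neurexin gene, a junction at 3R 18306849 to 18307563 took 85.0 ± 3.61% in wild type (288 reads, n = 4) and had no reads in the per0 polyA libraries. None of these junctions matched an intron record of the deposited table, and the gene name comes from other junctions of the cluster.

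The edgeR test called 315 of 1776 clusters in non-polyA and 18 of 348 in polyA. Of 226 genes tested in both, 10 were called in both against 4.66 for independent lists: Aldh-III, Caki, CG12194, CG31158, CG32016, CG34148, CG3662, cpx, Cyp28d1 and nrv3. This counts gene names, whichever junction changed. The junction with the smallest p was the same, with the same direction, for CG12194, CG32016, CG3662, Cyp28d1 and a cluster of CG34148. It differed between the protocols for Aldh-III, Caki, CG31158, cpx and nrv3. The polyA count was 10 without wild-type ZT0 replicate 1, 34 without wild-type ZT12 replicate 1 and 11 without per0 ZT12 replicate 1. Junction read numbers are counts without molecular identifiers, and a junction with 0 reads was not detected at this depth.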

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

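Of the tests in this part, those of whether both protocols saw the time-of-day change and of a single library as its source were chosen only after the result was seen.

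For 5 genes the 24-h component in the non-polyA libraries differed between wild type and per0 by a test of the difference itself: tim (peak minus trough of the difference 4.77 on the log2 scale), Clk (3.42), CG17386 (4.67), Dro (3.64) and CG11407 (4.16). Their calls were lost without 1 library in 2 of 16 runs for tim, 7 for Clk, 7 for CG17386, 12 for CG11407 and 11 of the 14 that tested it for Dro. CG17386 was still lower at ZT12 in per0 polyA brains (log2 -2.65, against -4.26 in wild type), while in per0 non-polyA brains ZT12 minus ZT0 was 0.70 (SE 0.39). In the polyA libraries ZT12 minus ZT0 differed between the genotypes by the same kind of test for 28 genes, of which the 21 taken by the naming rule are given. More positive in per0 were CG15784 (4.85), CG10513 (4.42), CG14329 (4.13), ImpL3 (3.92), CG11407 (3.67), mir-281aS (3.39), Arc2 (2.62), Arc1 (2.58), Hsp22 (2.16), Clk (2.12), CG6040 (2.08) and CG31869 (1.75). More negative in per0 were vri (-4.42), tim (-3.48), gol (-3.17), IM4 (-3.06), CG4476 (-2.81), cln3 (-2.46), CG6074 (-2.45), CG32444 (-2.15) and CG5798 (-1.76). Genes near the threshold lost their call when 1 library was left out, CG31869, CG5798 and Clk in 6 of 8 such runs, CG6040, Hsp22 and mir-281aS in 5, CG32444, CG6074 and cln3 in 4, Arc1 in 3, CG4476 in 2 and Arc2 and IM4 in 1. The call of mir-281aS also ended in edgeR (adjusted p = 0.75), with a pseudocount of 2 (0.0995), median-ratio (0.0527) or quantile scaling (0.053) and no filter (0.0635). No filter ended those of CG31869 (0.0635), CG6040 (0.0608) and Clk (0.065), and the median over records (0.0802) or a replicate block (0.0639) that of Clk. For the 24-h component, the call of Dro ended in edgeR (0.771) and with a pseudocount of 0.1 (0.494) or sample weights (0.115), and that of CG11407 with no filter (0.0737), a pseudocount of 0.1 (0.0531) or a replicate block (0.0578).

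One pattern was weighed here, the 15 genes called higher at ZT12 than ZT0 in per0 polyA brains, among them CG15784 and Hsp22, called higher in wild type too, and ImpL3, Arc1 and Arc2. A single library as the source was argued against for 6 genes, CG15784, Hsp22, ImpL3, Arc1, Arc2 and CG1942, each called in all 4 tests of all genes without 1 per0 library (log2 at least 2.62, adjusted p up to 0.0354). For the other 9 it cannot be told apart from a loss of power: each lost its call in at least 1 such test, and all did without ZT0 replicate 1. Their median log2 was 1.92, 1.85, 2.03 and 1.75 without ZT0 replicate 1, ZT12 replicate 1, ZT0 replicate 2 and ZT12 replicate 2. Since these genes were picked with all libraries, such sizes cannot decide it. Genes called anew with 1 library of each time, a different set from these 9, had medians of 2.72 to 3.82 in the 2 left aside. Their lower quartile there was -1.18 when called with ZT12 replicate 2 and ZT0 replicate 1, and 0.567 or more in the other pairings. A time-of-day change of per0 brains seen by both protocols cannot be told apart from one in polyA alone: the 8 genes tested in non-polyA had a median there of 0.206, or 0.106 of their polyA median of 1.94, but the 34 genes called higher in wild type and tested there reached only 0.379 of theirs, 13.5% of random draws of 8 of them came as low, and the other 7 per0 genes, with CG15784, Hsp22, ImpL3 and Arc2, had a non-polyA mean under 1 RPKM. All 8 tested genes lay under 0.5 of their own polyA change. Of the 6 genes kept above, only Arc1 was tested in non-polyA, at -0.04 (SE 0.58) against 3.04 (SE 0.22) in polyA. A first bound at 0.5 of the polyA median, also set after the result, went against a change seen by both protocols. It was replaced by the random draws because the wild-type genes missed it too. The per0 ZT12 brains may differ from the others in how they were collected or in an effect of genotype, and neither was tested.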

How the results depend on the processing

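Chosen only after the result was seen were the omission of per0 ZT0 replicate 2 with wild-type ZT6 replicate 1, the settings for the overlap of the protocols, the list test for time in per0 and the list test without single libraries.

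For named genes, 4291 comparisons with an alternative kept their side of the threshold, 323 lost the call and 34 gained it. The sign turned for per between protocols, called at 0.82, at -0.14 with quantile normalization and -0.34 with median-ratio scaling, and for tim, not called at 0.32, at -0.57 and -1.22, both past the threshold, where median-ratio scaling moved the median of all genes by -1.43. It also turned in 15 comparisons of Pdp1, cyc or vri that passed neither before nor after.

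With fewer genes tested (mean of at least 5) the genotype count in non-polyA was 574, the wild-type 24-h count 7, that of per0 0 and the calls shared by the protocols 97. An adjusted p under 0.1 gave 1655 for genotype in non-polyA, 157 for ZT12 in wild type and 43 for its genotype difference. No filter gave 51 for ZT12 in wild type, 35 in per0 and 3 for the per0 24-h component. That component counted 0 with a pseudocount of 2, quantile normalization, median-ratio scaling or sample weights, and the wild-type one 25 with sample weights. Its genotype difference counted 3 with a pseudocount of 0.1 and 8 with quantile normalization. Without per0 ZT0 replicate 2 and wild-type ZT6 replicate 1 the wild-type component counted 7 and the difference 0. List calls numbered 4 with an estimated correlation, against 41. Exon usage counted 624 in non-polyA with an exon mean of at least 5 and 1176 in polyA with a pseudocount of 2. Junctions counted 180 in non-polyA with at least 20 reads, and in polyA 39 with at least 5 and 9 with at least 20. With limma as planned, unadjusted p was under 0.05 for 269 of 9323 genes for the per0 component and 414 for the difference. Both shares lie below the 0.05 that no effect would give on average. The cause of the changes in count between settings was not tested.

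Leaving out 1 library at a time gave 729 to 1417 for genotype in non-polyA and 1051 to 2612 in polyA, 7 to 22 for the wild-type 24-h component, 0 to 171 in per0 and 0 to 66 for their difference. It gave 17 to 859 for ZT12 in wild type, 8 to 46 in per0 and 10 to 77 for their difference, 658 to 1454 for exon usage in non-polyA and 384 to 1488 in polyA, and 10 to 34 for polyA junctions. In each such run the lone library of a group was assumed to vary like the other groups, and the cause was not tested. Junctions in non-polyA (246 to 335) and the protocol comparison (9010 to 9310) stayed within 1.5 times their count, as did the 41 list calls (37 to 47), of which 20 held in all such runs and 21 were lost in at least 1.

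A replicate block ended the calls of per (adjusted p = 0.0576) and CG10513 (0.0576) in the wild-type 24-h component, CG11407 in its genotype difference (0.0578), Clk in the ZT12 difference (0.0639) and between protocols (0.0531), and MRP at ZT12 in per0 (0.0679), and no other call on the level of a named gene.

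Counting reads that map to several places was not run. With 2 libraries per group at these depths the time tests miss many changes: simulated 2-fold changes were called in 1.49% of cases for the wild-type 24-h component and in 28.4% for ZT12 minus ZT0 in wild type.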

Other observations

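Of the tests in this part, that of retina carried over was chosen only after the result was seen.

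Other splits of the libraries into groups of the same sizes, with time in the model, tested whether chance can give as many calls. For genotype in non-polyA 1 of 100 splits, the real one, gave as many (1223 calls, highest other 104), and in polyA 1 of 35 (1892, highest other 1). For the protocols it was 1 of 35 (9277, highest other 0), for exon usage 1 of 100 in non-polyA (1026, highest other 544) and 1 of 35 in polyA (756, highest other 73), and for junctions 1 of 100 (288, highest other 66) and 1 of 35 (19, highest other 2). The real split thus gave the most calls in each test, which argues against chance as the source of a whole count. It does not show how many of the calls chance could give. The real difference stays in the spread of the other splits, which can lower their counts. The cause of the 544 exon usage calls in another split was not tested.

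The 208 genotype calls shared by both protocols in the same direction may come from per or from other differences between the strains. An excess of shared calls on the whole X chromosome was argued against, and with it strain variation mainly there. Shared calls were 27 of 1358 genes on X and 171 of 6743 on autosomes. The ratio was 0.784 (odds ratio 0.497 to 1.18) against a bound of 1.5, set after the calls but before their positions were looked at. Variation linked to per, within 2 Mb of it, cannot be told apart from no such excess, since 6 of 242 genes there and 201 of 8042 elsewhere give a ratio of 0.992 whose odds ratio spans 0.356 to 2.23 and so reaches past that bound. Strain differences on the autosomes, or on X without an excess there, and effects of per itself stay open and were not tested.

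Lower photoreceptor transcripts in the per0 polyA libraries (11 of 29 lower, adjusted p = 0.000303, and 0.918 with an estimated correlation; 1 member is in another list) could come from less retina left on those brains, which would lower all of them alike. The median of the 28 other members was -0.52 (quartiles -0.76 to -0.09), 0.265 above ninaE at -0.78 (SE 0.27, adjusted p = 0.0689), where the bound set for that explanation allows 0.5. That bound is about as large as the median change itself, and the upper quartile lies further above ninaE than it allows. The test thus cannot decide, and less retina on those brains stays open. ninaE stood at 16344 ± 2418 RPKM in per0 and 28111 ± 4147 in wild type (n = 4 each). In the separate non-polyA libraries ninaE did not pass (log2 -0.01) and the list had a median of -0.15 (adjusted p = 0.0859). A change of photoreceptor transcripts in per0, and the y and w markers of that strain, stay open and were not tested.

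Neuropeptide genes went both ways between genotypes in polyA, with 6 of 33 higher and 8 lower in per0 (8 and 8 adjusted over the list alone), a median of -0.03 and a mean of 0.09. Ast-C was at 187 ± 25.8 RPKM in per0 and 73.9 ± 6.03 in wild type, and Fmrf at 17.4 ± 1.99 and 30.9 ± 2.96 (n = 4 each). Of 14 hemocyte and trachea markers 4 were called in polyA, all lower in per0, among them eater (2.92 ± 1.11 and 7.83 ± 2.64) and Hml (2.66 ± 0.642 and 8.09 ± 4.33; n = 4 each), and the list did not pass (median -0.14, adjusted p = 0.314). In the same libraries immune genes, lower as a list in non-polyA per0, had 6 of 26 higher and 5 lower and a median of 0.06 (adjusted p = 0.612).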
